A study of Mus musculus with 2 samples.

How the data were processed

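DNase-seq libraries of 2 biological replicates of the mouse cell line MN1, both treated with 10 nM methyltrienolone, were used. The labels give the line, the treatment, the strain and the biological replicate number, but no tissue, and no untreated library was analysed here. With 1 group, no comparison between conditions was possible. Values are compared between the libraries, between genes and between peaks and their flanks.

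Per the listing deposited with each library, peaks and hotspots were derived from that library's filtered alignment to mm10 and a further input, and per the labels the assembly is mm10. The aligner and the peak caller are not given in the sources used here. Peaks and hotspots were deposited per library and not pooled, so each replicate's list stands alone. Each peak has a score deposited by the authors, a whole number from 1 to 150 in peaks of 150 bp, whose meaning is not given in the sources used here. It was used only to rank, describe and filter peaks within a list. A gene's promoter score in a replicate is that of its highest promoter peak there, which need not be at the same place in both. For each hotspot the authors deposited the −log10 of a false discovery rate (a q-value), for rates from 0.0500 down to 1e-06, with 100 written for 46.9% of the hotspots of replicate 1 and 44.7% of those of replicate 2. It was used only to see how hotspots were filtered. A list of called peaks depends on depth and on the threshold of the caller: a site without a peak is not shown to be closed, and sites in repeated sequence can be missing because reads cannot be placed there.

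Peaks on 21 main chromosomes were kept, and repeated entries (15 in replicate 1 and 26 in replicate 2) were counted once. All ends of peaks and hotspots lay within the chromosome lengths of the reference, GRCm38, the assembly of mm10. Coordinates are 1-based. Gene models were those of GENCODE mouse release M21. Peaks of both replicates that overlapped by at least 1 bp were merged into shared regions. Overlap between replicates was compared with 100 random circular shifts of replicate 2 along each chromosome, with assembly gaps of at least 10 kb removed, and the position of shared regions with 100 shifts of these regions. A promoter was called open where a shared region overlapped the 1 kb on either side of any annotated TSS of the gene. Each gene list was compared with all other protein-coding genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 18 lists. Distal regions lay more than 2.5 kb from any TSS. Their number within 50 kb of the genes of a list was compared with 10000 random lists matched on promoter state. Hotspots found in both replicates were ranked by the smaller of both widths. For genes of the sex chromosomes, the share of 32 bp sequences within 1 kb of the 5' end that occur once on the main chromosomes was counted. Motifs were sought on both strands in the 150 bp around the centre of each distal region and in the flank 1 kb downstream, with an exact McNemar test and Benjamini-Hochberg adjustment over 18 motifs. The ARE and the CTCF, RFX and REST motifs were allowed 2 mismatches, the NFI and NRF1 motifs 1 mismatch and the other motifs none. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Wilson intervals at 95% cover counting error only.

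The lists, motifs, tests and alternatives were fixed before the data were examined, except those named as chosen later. The lists cover housekeeping, pan-neuronal, motor neuron, sympathetic and neuroblastoma, other neurotransmitter, neural crest and mesenchymal, glial, fibroblast, skeletal muscle, blood, hepatocyte, epithelial and prostate, pluripotency and germline, endothelial, androgen response, steroid receptor and cofactor, Hox and olfactory receptor genes. Motor neuron and neuroblastoma genes were included because lines of this name are used as motor-neuron-like cells. The symbol Tf of the hepatocyte list was not among the protein-coding genes and was left out. The genes named were, in each list, the 4 open genes whose lower percentile of promoter score over both replicates was highest and the first 3 in alphabetical order without a peak, with all Hox genes by cluster, the genes nearest to the 10 widest hotspots and 10 highest distal regions, and Fkbp5, Chat, Mnx1, Isl1, Hand2, Th and Nr3c1. Results of some genes and motifs that were tested are not reported here. Genes named for an element, for the number of distal regions near them, on the sex chromosomes or in stretches of CpG-rich promoters without a peak were chosen after their values were seen. Where a list is described briefly, only some of the genes the rule takes are printed.

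The steps were tested on simulated data. Planted overlaps of 30% and 70% of 20000 peaks were recovered as 30% and 70%. With promoters open at 60% of 21911 genes, lists of 20 genes open at 95% were called in 75.5% of 200 simulated lists and lists open at 20% in 79.0%, while unchanged lists were called in 0.5%. Planted ARE palindromes with at most 2 mismatches were all found in 20000 random sequences, which the search rule ensures. Random sequences without a planted palindrome, with equal base frequencies, held a match in 0.54%, against 1.38% of the flanks of distal regions. Alternatives were a 500 bp or 2.5 kb promoter window, only the gene's 5' end, the stronger 50% of peaks, a reciprocal overlap of 50%, centres within 20 bp, the same number of top peaks, hotspots in place of peaks, autosomes only, 100 kb in place of 50 kb, upstream or GC-matched flanks, promoter peaks, 1 mismatch fewer, and each replicate left out. Peaks on the mitochondrial genome and on unplaced sequences were left out of the comparisons, which use positions on the autosomes, X and Y.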

Results

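DNase I hypersensitive sites, stretches of open chromatin that the nuclease DNase I cuts more often than their surroundings, were mapped by DNase-seq in MN1, an immortalized mouse cell line. Both libraries came from cells treated with 10 nM methyltrienolone, a synthetic androgen, and they form 1 group of 2 biological replicates. No untreated library was analysed here, so the values are levels in treated cells and not responses to the androgen. The authors' peak list held 189930 peaks in replicate 1 and 171017 in replicate 2, of which 189648 and 170745 distinct peaks on the autosomes, X and Y were analysed. Each peak was 150 bp wide, and together they covered 28.1 Mb in replicate 1 and 25.2 Mb in replicate 2. The wider hotspot regions numbered 158286 and 142225, and every analysed peak overlapped a hotspot of its own library. Read numbers were not analysed here, so the sequencing depth behind the lists is unknown.

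Strong sites were found in both replicates and weak sites often in only 1 of them. Of all peaks, 68.7% of replicate 1 and 76.7% of replicate 2 overlapped a peak of the other replicate by at least 1 bp, a mean of 72.7% ± 5.64 (SD, n = 2). With the peaks of replicate 2 shifted at random along each chromosome, 2.05% of the peaks of replicate 1 found a partner on average, and none of 100 shifts exceeded 2.29% (one-sided permutation p = 0.0099, the smallest they can give). The share found in the other replicate rose with the authors' peak score from 23.4% (95% Wilson interval 22.8% to 24.0%) in the lowest decile of replicate 1 to 98.4% (98.2% to 98.6%) in the highest, and from 29.6% to 98.3% in replicate 2. The overlapping peaks merged into 127806 shared regions, of which 76123 (59.6%) lay more than 2.5 kb from any transcription start site (TSS) and are called distal.

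**Figure D1:**
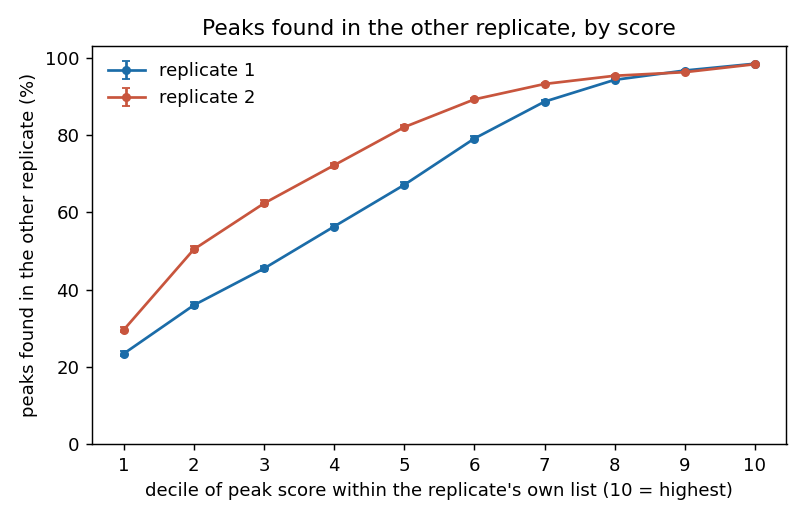
Share of peaks that overlap a peak of the other replicate (percent, vertical axis) by decile of the authors' peak score within each list (horizontal axis), for replicate 1 (blue) and replicate 2 (red), with 95% Wilson intervals. The share rose from 23.4% to 98.4% in replicate 1 and from 29.6% to 98.3% in replicate 2.

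Shared regions were concentrated at promoters and sparse on the X and Y chromosomes. Of the shared regions, 28.8% were centred within 1 kb of a TSS, against 6.38% ± 0.220 (SD over 100 random shifts), and 4.48% lay in exons, against 3.40%. Intergenic sequence held 28.7%, against 49.9% (two-sided permutation p = 0.0198 for each, the smallest the shifts can give). Introns held 38.0%, against 40.3% by shifts (permutation p = 0.0198), but this deficit was lost with a 500 bp promoter window (ratio 1.02, p = 0.178) and with the peaks of replicate 1 alone (ratio 1.00, p = 0.891). Among the autosomes the density ran from 37.1 shared regions per Mb on chromosome 3 to 83.6 on chromosome 11, with a median of 54.8. Chromosome X had 15.6 per Mb, 28.4% of that median, and chromosome Y 0.420 per Mb. Protein-coding genes numbered 5.80 per Mb on X and 2.08 per Mb on Y, against an autosome median of 8.03. The copy number of X and Y in these cells is unknown and mappability was not corrected for, so these densities do not show the state of the chromatin there. The widest hotspot found in both replicates covered the start of Tnrc18 (mm10 chr5:142815975-142824710), with 8734 bp in replicate 1 and 8719 bp in replicate 2. By the smaller of both widths, next came hotspots over the starts of Jun, a subunit of the AP-1 transcription factor (chr4:95047979-95054147, 6169 and 5924 bp), and Marcks, followed by Efna5, Midn (7082 and 5474 bp), Myc, Brd2, Zmiz1 and Arid2. The next in width was an intergenic hotspot 45783 bp from the nearest TSS, that of Rps6ka1 (chr4:133812548-133817746). The distal regions with the highest scores in both lists were nearest to Trappc9, Nr4a1, Wnt7b, Arid1a, Hspb1, Psma6, Insr, Irf2bp2, A4galt and Fignl2, and those near Arid1a and Insr lay in introns of these genes.

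Genes used by neurons in general had open promoters in these cells, while the genes of motor neuron and sympathetic identity were divided. Of 21911 protein-coding genes, 13035 (59.5%) had a shared region within 1 kb of a TSS. Of 26 pan-neuronal genes 25 did (96.2%), against 59.4% of all other genes (two-sided Fisher's exact test across genes, Benjamini-Hochberg adjusted p = 0.000221 over 18 lists). The highest scores among them were at Tubb3, a neuronal tubulin (149 in replicate 1 and 144 in replicate 2), Nefh, a neurofilament subunit (144 and 140), Syt1 and Scg2, and Dcx had no promoter peak. Of 24 motor neuron genes 13 had a shared promoter region (54.2%, exact adjusted p = 0.719). Isl1, a LIM homeodomain factor of motor and sympathetic neurons, scored 138 in replicate 1 and 137 in replicate 2 (chr13:116309676-116309825), and Onecut2, Ache and Etv4 were also among the highest, while Chat, the enzyme that makes acetylcholine, scored 102 in replicate 1 and 78 in replicate 2. Mnx1, Aldh1a2, Calca and Chodl had no promoter peak in either replicate. Of 24 sympathetic and neuroblastoma genes 16 were open (66.7%, exact adjusted p = 0.605), with Hand2 scoring 144 in replicate 1 and 138 in replicate 2 (chr8:57320896-57321045) and Alk, Mycn and Gata2 among the highest. Th had promoter peaks at different places in each replicate (29 and 26), and Dbh, Hand1 and Slc18a2 had none. All 20 housekeeping genes had a shared promoter region (exact adjusted p = 0.000221), the highest scores being those of Actb, Ppia, Rpl13a and Ywhaz. The tests compare genes within these libraries, since genes are not replicates. Against random lists matched on promoter CpG content, a comparison chosen after the data were examined, the pan-neuronal list stood at percentile 100, the housekeeping list at 99.7, the sympathetic list at 20.1 and the motor neuron list at 1.39.

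**Figure D2:**
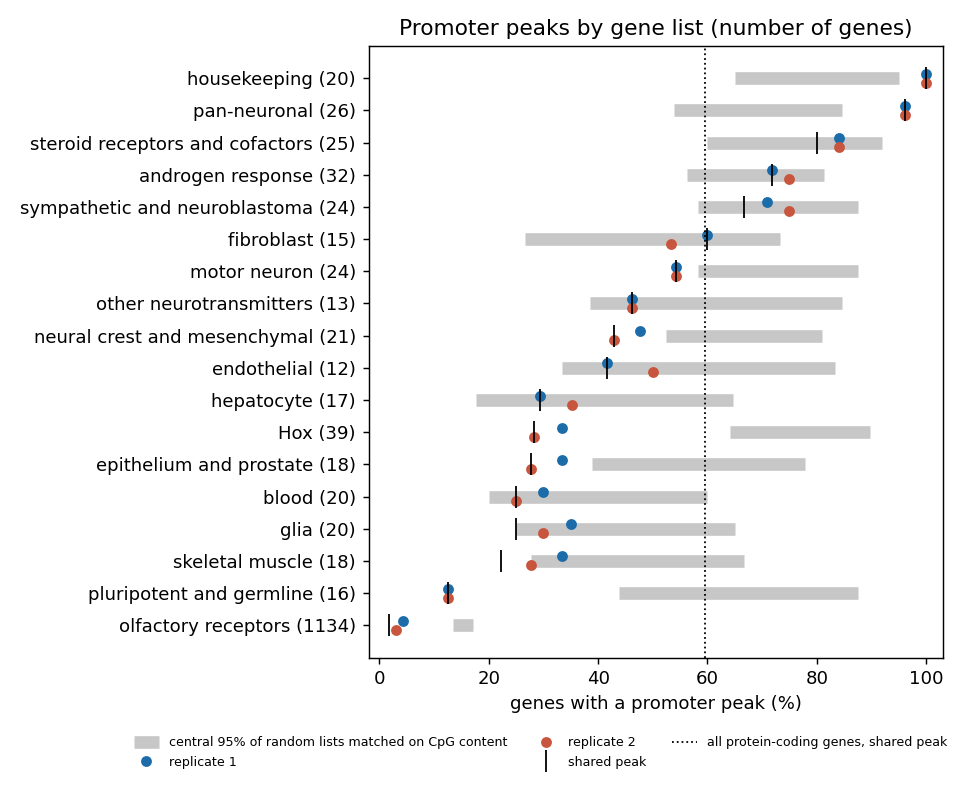
Percent of the genes of each list with a promoter peak in replicate 1 (blue points), replicate 2 (red points) and with a shared region (black ticks), beside the central 95% of random lists matched on promoter CpG content (grey bars) and the value of all protein-coding genes (dotted line). The pan-neuronal list lies at 96.2% and the olfactory receptors at 1.76%.

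Promoters of several other lineages were open less often than those of other genes. A shared region was found at 4 of 18 skeletal muscle genes, 5 of 20 glial genes and 5 of 20 blood genes (exact adjusted p = 0.00591 for each), at 5 of 17 hepatocyte genes (adjusted p = 0.0247), at 5 of 18 epithelial and prostate genes (adjusted p = 0.0153) and at 2 of 16 pluripotency and germline genes (adjusted p = 0.000534). Acta1, Chrna1 and Ckm of muscle, Cd34, Cd3e and Cd4 of blood, Alb, Ahsg and Apoa1 of liver, Cdh1, Cldn7 and Ehf of epithelium, and Dazl, Ddx4 and Dppa3 of the germline had no promoter peak in either replicate. Some members had promoter peaks in both replicates, among them Pax3 (130 and 112), Actn2 (139 and 126), Gfap (113 in both replicates), Tmem119 (138 and 132), Lck (133 and 124), Foxa3 (146 and 144), Krt8 (134 and 120) and Klf4 (135 and 127). Aif1, Aldh1l1 and Aqp4 of glia had none. Open members scored low for promoters. The median of the lower percentile was 77.4 for muscle, 87.1 for glia and 62.5 for blood. It was 81.6 for hepatocyte, 43.9 for epithelial and 79.0 for germline genes, against 94.7 over open protein-coding genes. Another 4 lists did not pass the test: 9 of 15 fibroblast genes (exact adjusted p = 1.00), with Fbln1, Fbln2, Col1a1 and Col1a2 highest and Col3a1, Loxl1 and Lum without a peak; 9 of 21 neural crest and mesenchymal genes (0.189), with Fosl2, Notch2 and Vim among the highest and Fosl1, Foxd3 and Meox1 without; 5 of 12 endothelial genes (0.316), with Esam and Vwf highest and Cdh5, Emcn and Flt1 without; and 6 of 13 genes of other neurotransmitters (0.480), with Tph2 and Hdc highest and Gad2, Slc17a6 and Slc17a8 without. Of 1134 olfactory receptor genes 20 had a shared region (1.76%, against 62.6% of other genes, a difference that passed the test), with Olfr556 (129 and 87), Olfr222, Olfr571 and Olfr630 highest, and Olfr1, Olfr10 and Olfr1000 without a peak. The calls of the glial and blood lists were lost with a promoter window of 2.5 kb (exact adjusted p = 0.322 and 0.171), those of the blood and hepatocyte lists with hotspots (0.0740 and 0.0774), and that of the hepatocyte list with the peaks of replicate 2 alone (0.0723). Against random lists matched on promoter CpG content, the glial (percentile 3.63), blood (5.71) and hepatocyte lists (15.9) lay within the central 95%, and the neural crest (0.345), skeletal muscle (0.845), epithelial (0.26) and germline lists (0.005) below it.

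Hox genes were open in 2 of their 4 clusters. Of 39 Hox genes 11 had a shared promoter region (28.2%, adjusted p = 0.000484, two-sided Fisher's exact test). Open promoters were found at 6 of 11 Hoxa genes (among them Hoxa4, Hoxa5, Hoxa6 and Hoxa7) and at 5 of 9 Hoxc genes (Hoxc4, Hoxc5, Hoxc6, Hoxc9 and Hoxc10), and at 0 of 10 Hoxb and 0 of 9 Hoxd genes. The Hoxc cluster held 31 shared regions (2.47 per 10 kb) and the Hoxa cluster 18 (1.56 per 10 kb), against 6 in Hoxb (0.326 per 10 kb) and 4 in Hoxd (0.374 per 10 kb). Hoxc10 and Hoxc5 shared their strongest promoter peak (chr15:102966576-102966725, scores 142 and 136), since an annotated Hoxc5 transcript starts beside Hoxc10. Hoxa2, Hoxa11 and Hoxa13 had no promoter peak in either replicate.

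**Figure D3:**
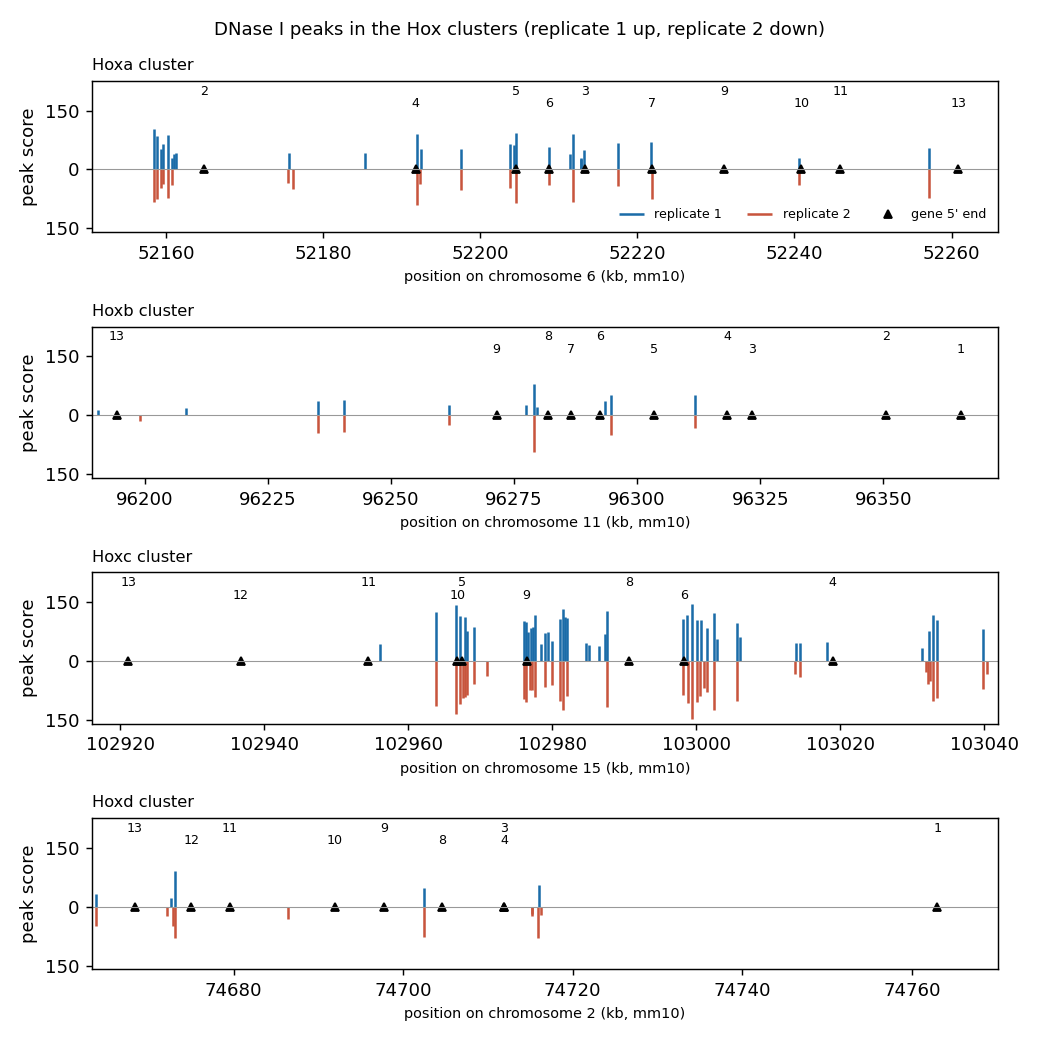
Peaks of replicate 1 (blue, upward) and replicate 2 (red, downward) in the Hox clusters, drawn at their position (kb, mm10) with the authors' peak score as height; triangles and numbers mark the 5' ends of the Hox genes shown. Peaks are dense in Hoxc and Hoxa and sparse in Hoxb (6 shared regions) and Hoxd (4).

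The promoter of Nr3c1, the glucocorticoid receptor, was open in both replicates, with its highest peak at chr18:39491576-39491725 in replicate 1 and at chr18:39489876-39490025 in replicate 2. Of 32 genes known to respond to androgens 23 had a shared promoter region (71.9%), which did not pass the test (adjusted p = 0.286, two-sided Fisher's exact test). Fkbp5, a cochaperone of steroid receptors and a common androgen target (147 and 140), Acsl3, Per1 and Sgk1 had the highest scores, and Ell2, Homer2 and Ndrg1 had no promoter peak. Of 25 steroid receptor and cofactor genes 20 were open (80.0%, exact adjusted p = 0.0673), led by Srd5a1, Stub1, Dnajb1 and Hsp90ab1, with Nr3c2, Pgr and Srd5a2 without a peak. That list passed the threshold with the peaks of either replicate alone (exact adjusted p = 0.0378 without replicate 2 and 0.0399 without replicate 1) and with a 500 bp window (0.0419). The androgen response genes had 5.41 shared distal regions within 50 kb on average, against 4.72 in random lists matched on promoter state (percentile 81.6 of 10000 lists), and within 100 kb they had 12.7 against 9.73 (percentile 97.9). The percentile was 68.2 with the stronger 50% of peaks. No other list was compared at 100 kb. At 50 kb all lists but Hox and olfactory receptors lay above the middle of their random lists, so 97.9 does not show an excess particular to androgen response genes. Distal regions with an androgen response element (ARE), the palindrome AGAACANNNTGTTCT bound by steroid receptors, lay within 50 kb of 5 of the 32 genes, with 0.156 per gene against 0.153 in random lists (percentile 55.0). All 5 elements had 2 mismatches to the palindrome, the most allowed, and 1.38% of flanks of distal regions also held a match by this rule. At Fkbp5 the element AGAACACAGTGTCCC lay in an intron (chr17:28513902-28513916), in a region scored 40 in replicate 1 and 90 in replicate 2. An intron of Zbtb16 held AGGACACAGTGGTCT (chr9:48786984-48786998, scores 24 and 69). In intergenic sequence AGCACTGGCTGTTCT (chr8:94197775-94197789, scores 67 and 99) lay in a region centred 25177 bp from the TSS of Mt2. The others were AGCACACTCTGTTCC near Aldh1a3, in an intron of Lrrk1 (chr7:66384443-66384457, scores 39 and 64), and AGAAAATCCTATTCT near Camkk2, in an exon of Gm43684 (chr5:122784008-122784022, scores 28 and 27).

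Distal open chromatin was rich in sites of NFI, RFX, EBF, CTCF and AP-1 factors. Compared with flanks 1 kb downstream, NFI palindromes were 9.01 times as frequent (3.32% of 76123 regions against 0.369%), RFX palindromes 7.63 times (adjusted p = 2.14e-120, two-sided exact McNemar test, as for all motifs), EBF sites 6.30 times (2.8e-251), CTCF sites 6.04 times (11.2% against 1.85%) and AP-1 sites 5.35 times (14.5% against 2.70%). The CRE of CREB and ATF factors was 4.11 times as frequent (4.86e-40). The ARE was found in 3.50% of regions (95% Wilson interval 3.38% to 3.64%) against 1.38% of flanks, a ratio of 2.54 (9.97e-164). Its ratio was 1.96 with the distal peaks of replicate 1 and 2.91 with those of replicate 2. Smaller ratios were found for SP/KLF boxes (2.07), ETS sites (1.93), REST sites (1.79), NRF1 sites (1.74), the NEUROD-type E-box (1.70), the TAATTA homeodomain core (1.29) and TEAD sites (1.17, exact adjusted p = 0.0163), and NFY boxes did not differ detectably from flanks (0.99, adjusted p = 0.639). GATA sites had a ratio of 1.05 (exact adjusted p = 3.35e-05), which turned to 0.975 with the peaks of replicate 1 alone (adjusted p = 0.0122). With flanks matched on GC content, since peaks held 50.2% GC and flanks 45.5%, the ratio was 1.24 for SP/KLF boxes, 2.36 for the TAATTA core and 1.45 for GATA sites, and NRF1 sites lost their call (1.18, exact adjusted p = 0.0787). TEAD sites lost theirs with upstream flanks (exact adjusted p = 0.283) and with the stronger 50% of peaks (0.680), and NFY boxes passed the threshold in opposite directions with the stronger 50% of peaks (1.07, 0.0328) and without replicate 2 (0.957, 0.0141). With 1 mismatch fewer the ratio was 7.84 for the ARE, 18.8 for CTCF, 20.3 for NFI and 2.93 for REST sites. The number of mismatches allowed differed between motifs, so the ratios do not rank the factors. By score within each list, the ARE share of shared distal regions fell from 5.85% in the lowest decile of replicate 1 to 1.59% in the highest, and in replicate 2 it was 2.40% in the lowest decile and 3.52% in the highest.

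**Figure D4:**
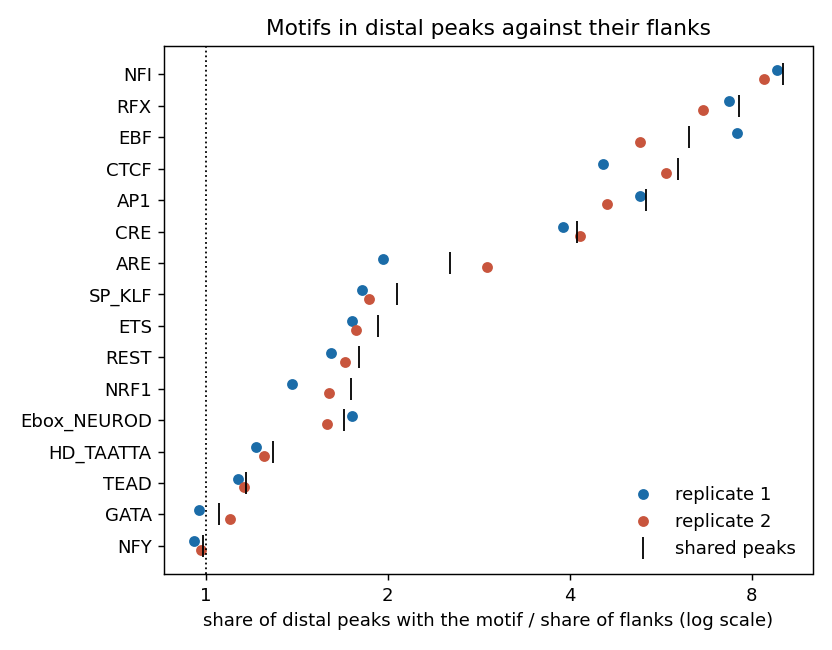
Share of distal peaks with each motif divided by the share of flanks 1 kb downstream (log scale), for shared regions (black ticks) and for the distal peaks of replicate 1 (blue) and replicate 2 (red) alone. With these flanks NFI lies at 9.01 and NFY near 1, and the ARE lies at 1.96 in replicate 1 and 2.91 in replicate 2.

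The distal peaks found in only 1 replicate carried different motifs, a comparison chosen after the data were examined. Peaks that met neither a peak nor a hotspot of the other replicate numbered 52029 in replicate 1, of which 38915 were distal, and 29977 in replicate 2, of which 21449 were distal. The ARE was in 5.78% of the distal peaks found only in replicate 2 and in 1.35% (95% Wilson interval 1.24% to 1.47%) of those found only in replicate 1, a ratio of 4.28 (adjusted p = 1.21e-197, two-sided Fisher's exact test), while the flanks of the former held 1.34%. CTCF sites (7.88% against 2.47%) and GATA sites (18.5% against 13.2%) were also more frequent in the peaks of replicate 2 only. EBF sites (0.769% against 3.69%), RFX palindromes (0.340% against 0.923%) and AP-1 sites (7.17% against 13.2%) were less frequent there. Of 18 motifs, 10 differed at an adjusted p below the threshold of 0.05 (two-sided Fisher's exact test), 3 of them higher and 7 lower in the peaks of replicate 2 only. With peaks matched on GC content 4 were higher and 8 lower: the ratio was 1.43 for SP/KLF boxes, in place of 0.867, and 1.08 for GATA sites. The test compares 2 libraries and not conditions, and the labels name the Illumina HiSeq 2500 and NextSeq 500 for replicate 1 and no instrument for replicate 2, so a sequencing batch and the replicate cannot be told apart.

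**Figure D5:**
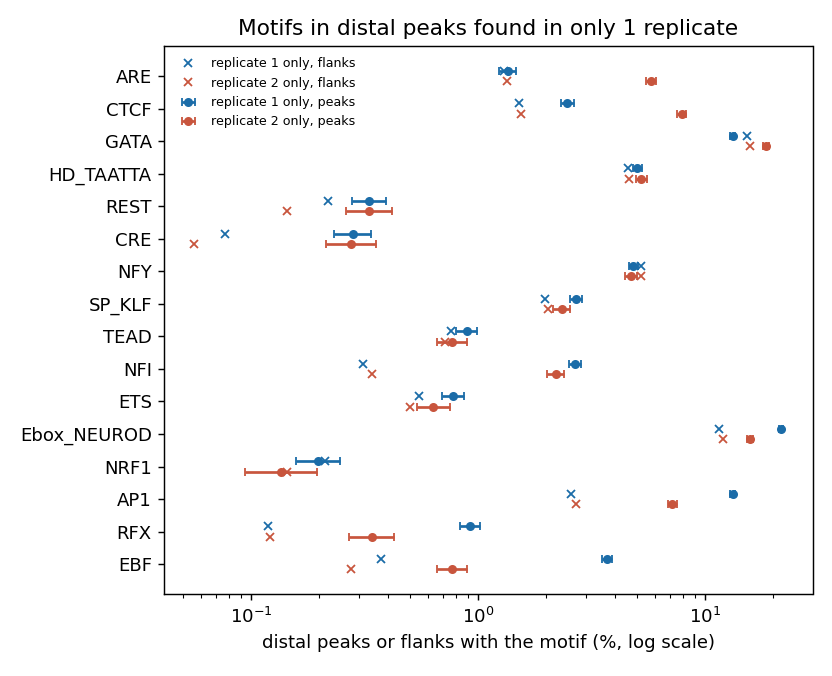
Percent (log scale) of distal peaks found only in replicate 1 (blue) or only in replicate 2 (red) that hold each motif (points, 95% Wilson intervals), and of their flanks 1 kb downstream (crosses). The ARE is at 1.35% in replicate 1 only and 5.78% in replicate 2 only, and EBF at 3.69% and 0.769%.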

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

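Peaks also lay on sequences that no comparison used. The mitochondrial genome carried 17 peaks in replicate 1 and 17 in replicate 2, each list having a median score of 150 there, and unplaced sequences carried 250 and 229 peaks. They are given because no comparison used them, and no test of their number was made. No explanation was tested for them.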

How the results depend on the processing

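The test against lists matched on promoter CpG content was chosen after the results were seen. The share of peaks found in the other replicate stayed above that of shifted peaks in all 6 alternatives, and 133 of 144 alternatives for the gene lists and 114 of 126 for the motifs kept their direction and side of the threshold. The mean number of peaks per replicate fell to 90349 with the stronger 50% of each list, by construction. In the cases below the cause was not tested. The ratio of introns turned to 1.02 with a 500 bp promoter window and ran from 0.959 to 1.00 with either replicate left out. Odds ratios with a 2.5 kb window lost their call for the glial list (0.578) and the blood list (0.477) and changed direction for the fibroblast list (2.07) and the endothelial list (1.09), none of them past the threshold. With hotspots the odds ratios of the blood list (0.371) and the hepatocyte list (0.378) missed the threshold, and with a replicate left out that of the hepatocyte list ran from 0.270 to 0.364. The endothelial list passed it with the stronger 50% of peaks (0.190), and the steroid receptor list with a 500 bp window (2.73) and with either replicate left out (2.94 to 3.08). Against random lists matched on promoter CpG content, the motor neuron (percentile 1.39) and neural crest lists (0.345) fell outside the central 95% of these lists, the glial (3.63), blood (5.71) and hepatocyte lists (15.9) no longer did, and the sympathetic (20.1) and fibroblast lists (83.6) changed direction. Distal regions near androgen response genes reached percentile 97.9 within 100 kb, a distance at which no other list was compared. Motif ratios in promoter peaks turned for GATA (0.697), TAATTA (0.738), TEAD (0.823) and NFY (1.77). With the stronger 50% of peaks the ratios were 1.02 for GATA and 1.04 for TEAD, both without a call, and 1.07 for NFY, with a call. With upstream flanks TEAD had 1.07, without a call, and NFY 1.00, and with GC-matched flanks NRF1 had 1.18, without a call. With either replicate left out, GATA ran from 0.975 to 1.10 and NFY from 0.957, with a call, to 0.981. The X chromosome density ran from 28.9% to 31.1% of the autosome median with either replicate left out. Of 125 named genes, 29 changed their promoter state in at least 1 of 8 alternatives. Read depth is unknown, and a weak site absent from a list is below what that list could show.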

Other observations

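The tests of the Y chromosome, of lists matched on promoter CpG content, of distal regions near lists other than the androgen response list, and of the ARE in peaks found in only 1 replicate were chosen only after the results were seen. Several lists of unlike lineages, the sympathetic list among them, had more distal regions near their genes than random lists. The random lists were drawn from all protein-coding genes, among them 1134 olfactory receptor genes with a mean of 0.496 such regions. All lists but the Hox and olfactory receptor lists lay above the middle of their random lists. A high percentile therefore does not show a density particular to a lineage. The 24 genes of the sympathetic and neuroblastoma list had 8.13 shared distal regions within 50 kb on average, against 4.53 in random lists matched on promoter state (percentile 99.98), with 17 near Ngfr, 16 near Chga and 15 near Slc18a2. The skeletal muscle list had 5.83 against 2.96 (percentile 99.7), with 20 near Acta1 and 18 near Pax3, the fibroblast list 6.93 against 4.30 (98.5), the glial list 5.10 against 3.07 (98.4) and the motor neuron list 5.92 against 4.10 (97.7). The percentiles of the other lists were 96.5 for blood, 94.2 for hepatocyte, 89.9 for housekeeping, 88.4 for endothelial, 87.0 for pluripotency and germline, 83.4 for pan-neuronal, 82.5 for epithelium and prostate, 65.8 for other neurotransmitters, 65.6 for neural crest, 58.4 for steroid receptors, 20.7 for Hox and 0 for olfactory receptors.

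AREs in distal peaks found only in replicate 2 included TGAACATTCTGTTCC in an intron of Dusp1 (mm10 chr17:26535328-26535342). Another was ATCACAAAGTGTTCT (chr8:94162649-94162663), in a peak centred 10013 bp upstream of the TSS of Mt2. Each had 2 mismatches to the palindrome. The 3 such peaks within 50 kb of the androgen response genes compare with 2.05 in random lists (percentile 74.9). The spacing of the half-sites mattered: with 3 bp between them the palindrome was 4.28 times as frequent in the peaks of replicate 2 only as in those of replicate 1 only, and with other spacings from 0 to 8 bp the ratio was at most 1.86.

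The ARE difference between the libraries was weighed against technical explanations, none of which was a difference named by the design, so no biological explanation was tested. A difference in the length of the peak lists is argued against by the same number of top peaks from each list, where the ratio was 4.78. That setting cut only the list of replicate 1. The hotspot lists, which also decide whether a peak was found in only 1 replicate, stayed of unequal length. In the stronger 50% of each list the ratio was 22.7 (68 of 632 peaks against 16 of 3383, Fisher's exact p = 5.89e-41). There the share was 10.8% in replicate 2 only, against 5.78% of all such peaks, and 0.473% in replicate 1 only, against 1.35%. These stronger peaks were not matched on GC content, and neither setting equalises read depth. Base composition is argued against by 29 palindromes with rearranged half-site letters, of which 0 gave a ratio as large (highest 2.91), and by a ratio of 3.68 in peaks matched on GC content. A shift of all factor-bound sites is argued against by the 7 motifs that were less frequent in the peaks of replicate 2 only, of which SP/KLF boxes turned with peaks matched on GC content (1.43) and NFI with 1 mismatch fewer (1.56), while 4 stayed lower past the threshold in each of 7 settings. The libraries did not differ in the ARE alone. CTCF sites differed in the same direction (ratio 3.19, and 4.66 in peaks matched on GC content) and EBF sites in the opposite direction (0.208). A difference in read depth, a sequencing or library batch, a difference between the cultures in the activity of a steroid receptor, and a wrong label stay open, since read depth is unknown and each side is 1 library.

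The share found in the other replicate differed by at least 68.7 percentage points between the highest and lowest deciles of score in each replicate. Weak peaks near the calling threshold would give this, but a rise with score does not tell them from other causes. They leave unexplained the ARE difference, which was larger in the stronger 50% of each list.

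Chromosome Y carried 60 peaks in replicate 1 and 48 in replicate 2, of which 47 and 38 lay in its last 2 Mb. Its first 4 Mb, where the short-arm genes lie, held 2 and 1. Of 8 short-arm genes, among them Ddx3y, Eif2s3y, Kdm5d and Uty, 0 had a promoter peak in either replicate, while all 7 X-linked homologs tested, such as Ddx3x (136 and 120) and Kdm6a (146 and 130), had one in both. Of the 32 bp sequences around the starts of Ddx3y, Eif2s3y, Kdm5d and Uty, 89.1% to 100% occurred once on the main chromosomes, so the 0 argues against low mappability of the Y chromosome as the cause there, while at Zfy1 (2.99%) and Uba1y (49.0%) it stays open. Cells without a Y chromosome are a candidate explanation, from a female animal or by loss in culture, and the labels do not give the sex. It was not tested, and the source of the Y peaks outside the last 2 Mb was not examined.

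CpG-rich promoters are often open in any cell, which could account for open promoters of a list. The pan-neuronal list stood at percentile 100 among lists of the same CpG content, which argues against this explanation. The sympathetic list stood at 20.1, within the range that CpG content gives. The motor neuron list stood at 1.39, below that range, so its lower share cannot be told apart from other properties of the list by this test.

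A search for 4 or more successive CpG-rich promoters without a peak in either replicate, made after the data were examined and passing over other promoters, found such promoters in the Hoxb, Hoxc and Hoxd clusters. Peaks lay between them in each replicate (5 and 2 in Hoxb, 26 and 19 in Hoxc, 5 and 10 in Hoxd), and in Hoxc the open promoters of Hoxc5, Hoxc9 and Hoxc10 were among those passed over. From Pcdha3 to Pcdha7 (chr18:36946105-36973802) there were 0 peaks in either replicate, and from Dock8 to Dmrt2 (chr19:24999534-25672411) 4 in replicate 1 and 0 in replicate 2. The stretches from Fam177a to Srp54c, Hist1h2bq to Hist1h2br, Gm3417 to Tcte3 and Gm10722 to Gm10718 also held 0 peaks in either replicate. How much of these stretches occurs once in the genome was not counted. Missing peaks there therefore do not show closed chromatin.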
